A study of Homo sapiens with 6 samples.

How the data were processed

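The samples were 6 cultures of human cell lines, JEG-3 and HTR-8/SVneo, each as control, with LIF at 50 ng/ml and with IL-6 at 100 ng/ml for 24 h, with 1 array per group. RNA was labelled by a sense-strand protocol for whole-transcript Affymetrix exon arrays, per the labels' protocols. The deposited values are log2 signals per probe set, as their range of 1.61 to 13.66 on the 6 arrays shows. The submitters' processing notes name RMA and GCRMA, with no version given and without saying which of them made these values, so the background correction behind them stays unknown. The genome build and the array's probe strand are not given in the sources used here, and no coordinates are printed.

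In the table used here 60139 probe sets carry 1 gene symbol, 1636 several and 3760 none. Only probe sets with 1 symbol were used. Of their symbols 3277 were current, 486 were updated through synonyms in a table of the GRCh38.p14 assembly and 17 were kept as given, and after symbols of the same gene were joined they name 3774 genes. According to it, 98.9% of the genes lie on chromosomes 1 to 4, and 26 lie elsewhere. Those 26 are uncertain, as their probe sets may read related sequences, and none of them is named as a finding. The other genes of the array were not analysed here. Genes had a median of 13 probe sets, and 61 genes had 1. For arrays there is no read depth, and their number limits the precision.

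Each gene was represented by its probe set with the highest mean over the 6 arrays, a rule set before the data were examined, as were the tests, the gene lists, the named-gene rule and most alternative settings. The mean over a gene's probe sets was among those settings and the median over them was chosen after seeing the data. Counts under all 3 summaries had been seen while the analysis was set up, and the mean had for a time stood as the main summary before the fixed rule was restored. The summaries give opposite splits of higher and lower genes in several comparisons, so the splits are printed side by side.

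Comparisons within a line are differences of 2 single arrays with no test. A gene entered when the higher of its 2 values reached the median of all values, 7.08, and counted as higher or lower at 1.5-fold. Models were fitted with limma 3.58.1 in R 4.3.3 on 3473 genes whose highest value reached that level, with Benjamini-Hochberg adjustment at 0.05. An additive model of line and treatment left 2 residual degrees of freedom, and the estimated prior degrees of freedom were infinite, so that these p-values rest on a spread pooled over all genes. The line count also asked for a 2-fold difference. The interaction model took the LIF and IL-6 arrays of a line as treated arrays. Since nothing says that cultures were repeated, the p-values measure only the scatter between these arrays, which may be technical or differ between the lines. Tested on simulated data with 200 changed genes among 3473, the line fit recovered 38.5% of 2-fold and 91% of 4-fold changes, the LIF fit 0% and 85.5%, the IL-6 fit 0% and 84%, and the interaction fit 0% of both. Recovery was counted by adjusted p alone, without the 2-fold rule. The simulated scatter was drawn gene by gene from the additive fit, which also holds any difference between the lines in response. These shares therefore do not give the power of the fits on these data.

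Of 32 fixed gene lists, 4 had no member in the table and 19 had the 3 measured members needed for a percentile. A list's median difference within a line was set among 10000 random lists of the same size matched on level, as a description of these arrays. Of 114 such percentiles 13 lay outside the central 95%, where 5.7 would lie if list members were as independent as randomly drawn genes. Members of a list can vary together and the comparisons share arrays, so 13 is not shown to exceed chance. In the additive fits lists were tested with camera at a preset correlation of 0.01 and with an estimated one. With an estimated correlation the test rests on the 2 residual degrees of freedom, so few lists could pass it. Correlations between responses that share a control array were set beside 100 simulations of unchanged arrays, with scatter taken from the LIF minus IL-6 difference of the line.

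Genes named in the text follow the fixed rule. It takes the 8 highest and 8 lowest differences of each cytokine within a line, 4 of each for LIF against IL-6, 12 of each between the lines, up to 6 of each over both lines, up to 2 high and 2 low members of each list, and the receptor, STAT3, protease and hormone genes set in advance, of which IL6R is in the table. A further selection was made after the values were seen. Of 140 gene and comparison pairs the rule named within the lines, 39 had the opposite sign with the mean or the median over probe sets and 4 had fewer than 3 probe sets or lay outside chromosomes 1 to 4, which left 97 from which the text takes its genes. Named outside that selection, and chosen after their values were seen, are list members that the rule did not take up (among them MUC20 with LIF in JEG-3 and NOTCH2 for LIF against IL-6 in JEG-3), MUC1 for LIF against IL-6 in HTR-8/SVneo, COL6A3 with LIF in JEG-3, UPK1B for LIF against IL-6 in JEG-3, the values of a gene in the line or comparison where the rule did not name it, IMPG2 with LIF over both lines, S1PR1 and CHI3L1. The alternatives changed the level filter, the normalization (quantile, centring, loess), the summary of probe sets, the thresholds and the model's variance trend, and left out each array in turn. Figures were drawn with matplotlib 3.10.9.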

Results

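Gene expression was measured in 2 trophoblast-type human cell lines after treatment with leukemia inhibitory factor (LIF) or interleukin 6 (IL-6), both of which signal through the shared receptor subunit gp130 and the transcription factor STAT3. JEG-3 is a choriocarcinoma line, and HTR-8/SVneo is an immortalised line derived from first-trimester trophoblast. After serum starvation each line was left untreated, given LIF at 50 ng/ml or given IL-6 at 100 ng/ml for 24 h, and each of the 6 groups has 1 array, so that no group has a replicate. The table used here holds log2 signals of exon-level probe sets, 60139 of which name a single gene, for 3774 genes, 98.9% of which lie on chromosomes 1, 2 and 3 and part of chromosome 4. The rest of the genome was not analysed here, so most gp130 pathway genes, including LIFR, IL6ST, STAT3 and SOCS3, have no value below. The median probe set signal was 7.24, 6.99 and 6.93 on the control, LIF and IL-6 arrays of JEG-3 and 7.11, 7.05 and 7.19 on those of HTR-8/SVneo. Across probe sets the arrays of JEG-3 correlated at r = 0.955 (control and LIF), 0.937 (control and IL-6) and 0.972 (LIF and IL-6), and those of HTR-8/SVneo at 0.977, 0.981 and 0.971. Each gene is represented by its brightest probe set unless the mean over its probe sets is named, and all differences are on the log2 scale. The brightest probe set often gave the larger difference: of the 97 pairs of gene and comparison from which the genes named within a line were taken, 58 were under 1.5-fold with the mean over probe sets, 61 with the median and 52 with both. The number of arrays limits the precision of every value, and the comparisons within a line have no replicate check and no p-value.

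IL6R, the IL-6 receptor, was measured in both lines at similar levels. Its signal was 9.33, 9.38 and 9.69 on the control, LIF and IL-6 arrays of JEG-3 and 9.36, 9.40 and 9.37 on those of HTR-8/SVneo. JAK1, a kinase bound to gp130, lay at 11.19 in control JEG-3 and 11.51 in control HTR-8/SVneo.

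LIF against control in JEG-3 addresses which genes LIF changes in the choriocarcinoma line. MUC1, a membrane mucin of the uterine and placental surface and a STAT3 target, had the largest difference, with 8.27 in control and 11.13 with LIF, a difference of 2.86. All 22 of its probe sets were higher, with a mean difference of 1.70 over them. PARP9 and DTX3L, whose protein products form a complex in the interferon and DNA damage responses, were higher by 2.51 and 1.61. For PARP9 2 of 3 probe sets were higher, with a mean of 1.03, and for DTX3L 15 of 15 were, with a mean of 1.21. GUCA2A, the precursor of guanylin, was higher by 1.53 in 5 of 5 probe sets. ZEB2, a transcription factor of mesenchymal cells, was higher by 1.11 in 16 of 17 probe sets, and INHA, the inhibin alpha subunit, by 0.88 in 4 of 4.

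Genes that were lower with LIF in JEG-3 included PIGF, a gene of GPI anchor synthesis and not the placental growth factor, at −1.62. CD302, a lectin receptor, differed by −1.40 with none of 8 probe sets higher, and ST6GAL1, a sialyltransferase, by −1.36 with none of 11 higher. MBD4, a DNA glycosylase, differed by −1.25, DHX57, a helicase-type gene, by −1.28, and ID2, an inhibitor of helix-loop-helix transcription factors active in trophoblast, by −0.67.

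Among the gene lists, 2 of the 4 measured STAT3 target and feedback genes were at least 1.5-fold higher with LIF in JEG-3. These were MUC1 and CISH, a cytokine-induced feedback inhibitor, at 0.90, while BCL6 differed by 0.10 and MCL1 by −0.27. The list median lay at percentile 98.36 of 10000 random lists matched on level, and at 79.3 with the mean over probe sets. Of 4 mucins, 3 were at least 1.5-fold higher, with MUC13 at 1.24 (mean 0.20 over its probe sets) and MUC20 at 0.66 (mean 0.50) beside MUC1, and the list lay at percentile 99.99. The 7 cell cycle genes lay low, at percentile 0.23, and at 6.43 with the mean over probe sets. Only MCM6, a subunit of the replicative helicase, passed 1.5-fold among them, at −0.87. COL3A1 and LAMB3 of the extracellular matrix list were higher by 0.65 and 0.75, the latter with a mean of 0.12, but COL6A3 differed by −0.75 (mean 0.27, with 40 of 54 probe sets higher) and COL5A2 by −0.43, and the list lay at percentile 73.57. FAP, a fibroblast-type protease, differed by −0.63.

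In all, 365 genes were at least 1.5-fold higher and 154 lower with LIF among the 3371 genes compared in JEG-3. The direction of this split depended on the summary and the scaling. Relative to the median gene, which lay at 0.07, 261 were higher and 214 lower. With each gene's mean over its probe sets 11 were higher and 576 lower, and with the median 28 and 595. Quantile normalization gave 909 higher and 40 lower, centring each array gave 940 and 43, and loess centring gave 200 and 266. Centring moved the median gene to 0.33.

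**Figure D1:**
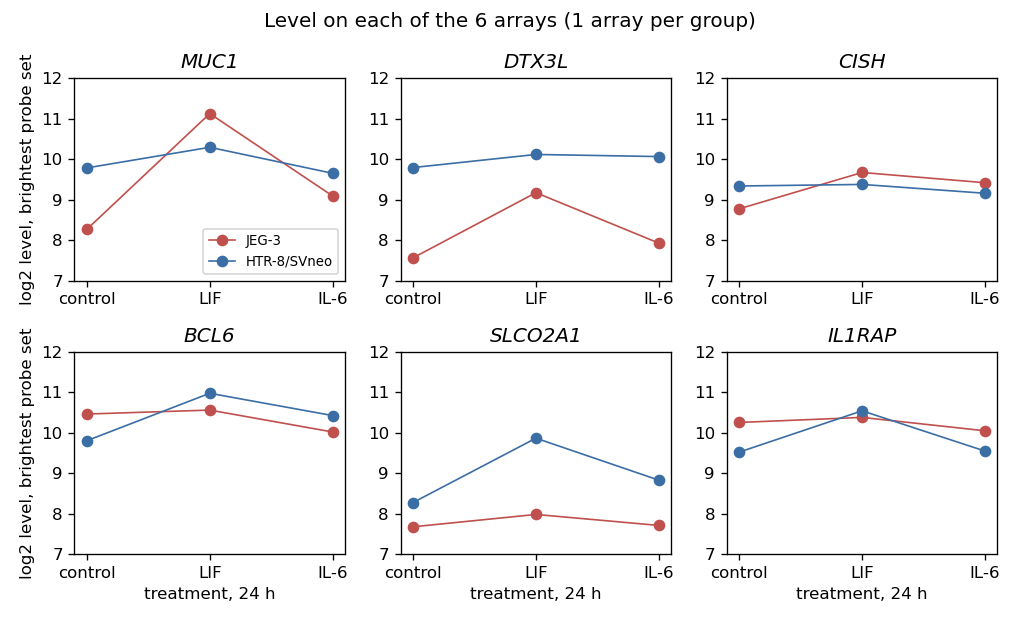
Log2 signal of the brightest probe set (vertical axis) of 6 genes in control, LIF and IL-6 cultures (horizontal axis), with 1 point per array and lines joining the 3 arrays of JEG-3 (red) and of HTR-8/SVneo (blue). MUC1 lies at 8.27 on the control array and 11.13 on the LIF array of JEG-3, while BCL6, SLCO2A1 and IL1RAP have their highest HTR-8/SVneo value on the LIF array.

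IL-6 against control in JEG-3 asks the same of IL-6. CCR1, a chemokine receptor, was higher by 2.65 in 3 of 3 probe sets, with a mean of 1.05. GYPC, a glycophorin of the membrane skeleton, was higher by 1.92 in 8 of 9 probe sets, CELF3, an RNA-binding protein, by 1.73 in 21 of 22, and FCMR, a receptor for IgM, by 1.67 in 13 of 15. The chemokine receptor CXCR6 was higher by 1.75, with a mean of only 0.46 over 5 probe sets. Lower genes included TASOR, a gene of epigenetic silencing, at −1.80 with none of 3 probe sets higher, and DCUN1D1, a neddylation factor, at −1.73 with none of 11 higher. CEP70, a centrosome protein, differed by −1.84, MBD4 by −1.94 and LEPR, the leptin receptor, by −1.70.

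The mucins were also high with IL-6 in JEG-3, which cannot count as a repeat of the LIF result, as both differences use the 1 control array and a low mucin signal on it would give both. For LIF against IL-6, without that array, the list lay at percentile 72.92. With IL-6, MUC20 was higher by 1.23 in 15 of 20 probe sets, MUC13 by 0.98 and MUC1 by 0.82 in 17 of 22, so that 3 of 4 passed 1.5-fold and the list lay at percentile 99.67. Of the STAT3 target and feedback genes, CISH differed by 0.64 and MUC1 by 0.82, while BCL6 differed by −0.44, and the list lay at percentile 89.89. JUN, an AP-1 factor, was higher by 0.63 and INHA by 0.92. PDK1, a kinase that limits pyruvate oxidation and belongs to the hypoxia and glycolysis list, differed by −0.88 with 1 of 21 probe sets higher, and the list lay at percentile 3.46. SERPINE2, a protease inhibitor of extravillous trophoblast, differed by −0.82, ITGB6 by −0.92, MCM6 by −0.75 and CASP8 by −0.73, with means over their probe sets of −0.22, −0.54, −0.74 and −0.41. CD2, a T-cell marker of the leukocyte list, was higher by 1.02, but turned to −0.010 once a gradient across genes shared by the lines was removed, an alternative chosen after seeing the data, and PTPRC, which marks all leukocytes, differed by 0.33.

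With IL-6, 662 genes were at least 1.5-fold higher and 429 lower among 3384 compared in JEG-3. Relative to the median gene, at 0.06, 538 were higher and 546 lower. The mean over probe sets gave 37 higher and 907 lower and the median gave 62 and 921. Quantile normalization gave 1406 and 96, centring each array 1343 and 135, and loess 497 and 496. Centring moved the median gene to 0.37.

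LIF against IL-6 in JEG-3 compares the cytokines directly, without the control array. MUC1 was higher with LIF by 2.04 in 20 of 22 probe sets, and PARP9 by 2.51 in 3 of 3. HEG1, a membrane mucin-like protein, was higher with LIF by 1.88 in 5 of 6 probe sets, with a mean of 1.41. FN1, fibronectin, was higher by 0.75 in 65 of 68 probe sets, with a mean of 0.80. BTG2, an antiproliferative p53 target, was higher by 0.77 in 7 of 7, and RPL11, a ribosomal protein, by 0.61 in 7 of 7. The 3 measured extravillous trophoblast genes, FN1, SERPINE2 and NOTCH2, were all at least 1.5-fold higher with LIF than with IL-6, at percentile 99.98 of random lists. Of these, SERPINE2 had 0.85 in its brightest probe set and a mean of 0.04 over 14. CCR1 differed by −1.46 with none of 3 probe sets higher, S100A4, a calcium-binding protein of mesenchymal cells, by −0.64, and the AP-1 genes JUN and ATF3 by −0.62 and −0.63, with means of −0.06 and −0.03. The third measured AP-1 gene, FOSL2, went the other way at 0.35, and the percentile of 0.18 for this list rests on the brightest probe sets of JUN and ATF3. In all, 180 genes were at least 1.5-fold higher with LIF and 116 lower. Quantile normalization gave 99 and 215, centring each array 132 and 177, the mean over probe sets 37 and 3, and the median 99 and 19.

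LIF against control in HTR-8/SVneo gave fewer genes past 1.5-fold. SLCO2A1, a prostaglandin transporter, was higher by 1.59 in 19 of 20 probe sets, with a mean of 1.12. BCL6, a transcriptional repressor and STAT3 target, was higher by 1.17 in 15 of 16, with a mean of 0.71. IL1RAP, the co-receptor for IL-1 and IL-33, was higher by 1.02 in 17 of 18, with a mean of 0.69. KCNJ3, a potassium channel, was higher by 1.54 in 6 of 7 and CRP, C-reactive protein and an acute phase gene, by 0.60 in 9 of 12. Among lower genes, SYT14 differed by −1.42 with none of 9 probe sets higher, TMEM40 by −1.19 with 1 of 13 higher and CD52, a surface glycoprotein, by −1.16, with a mean of −0.46.

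The STAT3 target and feedback genes stood high with LIF in HTR-8/SVneo, at percentile 99.72 and at 99.69 with the mean over probe sets. BCL6 alone of the 4 passed 1.5-fold, with MUC1 at 0.51, MCL1 at 0.14 and CISH at 0.04. The 6 hypoxia and glycolysis genes were all above the median gene, at percentile 99.25, with none past 1.5-fold. PFKFB4 differed by 0.55, HK2, hexokinase 2, by 0.36 and PDK1 by 0.25. The 4 mucins lay at percentile 99.08 and the 4 measured interferon-induced genes at 97.81, again with none past 1.5-fold. In all, 57 genes were at least 1.5-fold higher with LIF and 78 lower in HTR-8/SVneo. Quantile normalization gave 98 and 56, centring each array 91 and 55, the mean over probe sets 12 and 20, and the median 20 and 61.

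IL-6 against control in HTR-8/SVneo had BCL6 higher by 0.62 in 13 of 16 probe sets and ZMAT3, a p53 target, by 0.59 in 10 of 13. PARP15 was higher by 1.10 in 11 of 14. SLC15A2, a peptide transporter, differed by −1.0 with 6 of 24 probe sets higher and CNTN4, a neural adhesion molecule, by −0.96, with a mean of −0.25. The STAT3 target and feedback genes lay at percentile 9.79, with CISH at −0.18 and MUC1 at −0.13. Most probe sets of MUC1 went against that sign. With IL-6 19 of its 22 were higher, with a mean of 0.25, beside 17 of 22 and a mean of 0.28 with LIF. The 11 cytosolic ribosomal proteins lay at percentile 99.92, with a median of 0.21 relative to the median gene, and 1 of them passed 1.5-fold. In all, 69 genes were at least 1.5-fold higher with IL-6 and 58 lower. Quantile normalization gave 45 and 110, centring each array 45 and 89, loess 85 and 40, the mean over probe sets 10 and 4, and the median 53 and 10.

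LIF against IL-6 in HTR-8/SVneo placed the 4 STAT3 target and feedback genes on the side of LIF, at percentile 99.71 and at 91.1 with the mean over probe sets. This cannot count as a repeat of LIF against control, as both use the 1 LIF array of HTR-8/SVneo. Across all genes these 2 differences correlated at 0.648. BCL6 differed by 0.55 in 15 of 16 probe sets. MUC1 differed by 0.64 in its brightest probe set, but only 11 of its 22 probe sets were higher, with a mean of 0.03 and a median of −0.15. IL24, a cytokine of the IL-10 family, was higher with LIF by 0.88 in 13 of 13 probe sets, with a mean of 0.80, and HK2 by 0.72 in 23 of 25. TAFA1, a secreted neural protein, was higher by 2.11 in 6 of 7. IL1A, interleukin 1 alpha, differed by −1.93 with none of 6 probe sets higher, and TP63, a transcription factor of trophoblast stem-type cells, by −1.09 with 12 of 25 higher. In all, 134 genes were at least 1.5-fold higher with LIF and 117 lower. Quantile normalization gave 322 and 58, centring each array gave 284 and 59, the mean over probe sets gave 6 and 80, and the median gave 15 and 189. Centring moved the median gene to 0.14.

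**Figure D2:**
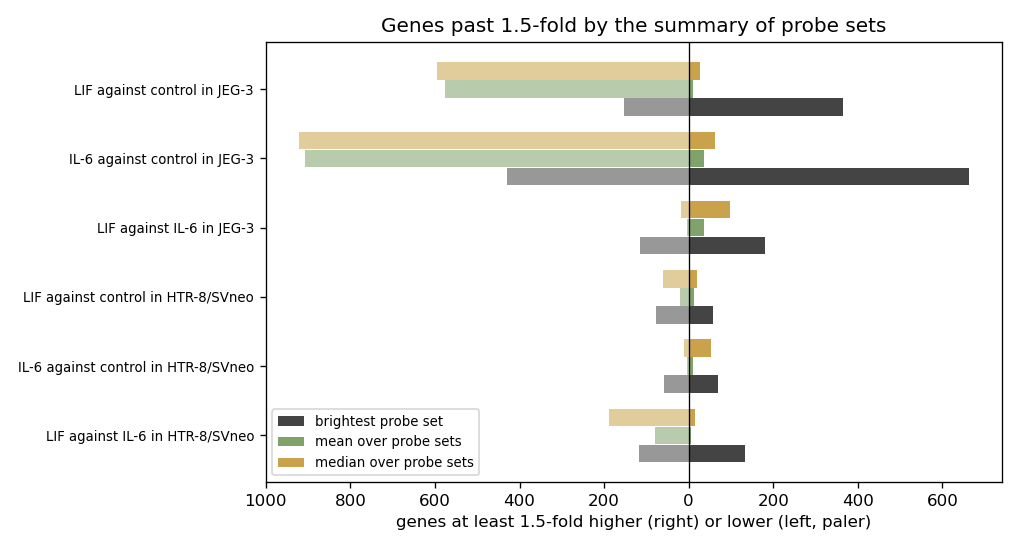
Number of genes at least 1.5-fold higher (right of 0) or lower (left of 0, paler) in each comparison within a line, for the brightest probe set (grey), the mean over probe sets (green) and the median over probe sets (ochre). For LIF against control in JEG-3 the brightest probe set gives 365 higher and 154 lower genes, and the mean over probe sets gives 11 and 576.

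With the lines as 2 observations of each response, 4 genes passed an adjusted p of 0.05 for LIF by limma with Benjamini-Hochberg adjustment over 3473 genes, all higher. MUC1 rose by 1.69 (SE 0.30, adjusted p = 6.0e-05), PARP9 by 1.5 (SE 0.30, adjusted p = 0.00087), KCNJ3 by 1.26 (SE 0.30, adjusted p = 0.026) and S1PR1, a sphingosine 1-phosphate receptor, by 1.25 (SE 0.30, adjusted p = 0.026). In its brightest probe set each of the 4 was higher on the LIF array in both lines, but the sizes differed. MUC1, PARP9 and S1PR1 had 2.86, 2.51 and 1.9975 in JEG-3. In HTR-8/SVneo they had 0.51, 0.5002 and 0.497, each under 1.5-fold, so their averages come mainly from JEG-3. Only KCNJ3 passed 1.5-fold in both lines, with 0.97 in JEG-3 and 1.54 in HTR-8/SVneo. The SE is pooled over all genes and does not reflect such a disagreement between the lines in a single gene. KCNJ3 also passed 1.5-fold with IL-6 against the same control arrays, at 0.61 in JEG-3 and 0.71 in HTR-8/SVneo. For LIF against IL-6 it had 0.37 in JEG-3, where its mean was −0.23, and 0.83 in HTR-8/SVneo, where its mean was 0.49. S1PR1 is given because the count is small, and its other probe sets do not support it: 2 of 6 were higher in each line, and over both lines the difference was 0.03 with the mean and −0.64 with the median over probe sets. PARP9 had 2 of 3 probe sets higher in each line, and over both lines 0.60 with the mean and 0.31 with the median. The mucin list was called higher by camera (adjusted p = 4.8e-07), as was the STAT3 target and feedback list (adjusted p = 8.1e-05), and neither was called with an estimated correlation (adjusted p = 0.71 for both). That version rests on 2 residual degrees of freedom, so it cannot tell whether correlation among genes accounts for the calls. Both lists have 4 measured genes and share MUC1, the only gene called in either, so the 2 calls are not independent. Without MUC1 the STAT3 list had BCL6 at 0.64, CISH at 0.47 and MCL1 at −0.07. The other mucins were MUC13 at 0.79, MUC20 at 0.51 and MUC4 at 0.38. No other list passed for LIF. The 4 genes were not called with the mean over probe sets, where the 1 gene called was CHI3L1, a secreted chitinase-like protein. No gene was called after quantile normalization or centring of each array, or without the control, LIF or IL-6 array of JEG-3 or the IL-6 array of HTR-8/SVneo. Without the HTR-8/SVneo control 22 genes were called, 3 of the 4 among them, without the HTR-8/SVneo LIF array 3 were called, 2 of them among the 4, and with a mean-variance trend 1 was called.

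For IL-6 over both lines IMPG2, a proteoglycan known from the retina, was the 1 gene called, and it fell by 1.33 (SE 0.30, adjusted p = 0.029 by limma). It was lower in both lines, but its mean over 23 probe sets differed by −0.12. It was not called after quantile normalization, after centring, with a mean-variance trend, with the stricter level filter, with the mean over probe sets or without any 1 of the arrays, and 5 other genes were called without the HTR-8/SVneo control. Of genes with the same direction in both lines that did not pass, TAF1A, a subunit of an RNA polymerase I factor, had −1.09 and SLAMF7 0.89. With LIF over both lines, against the same control arrays, TAF1A had −1.07 and IMPG2 −1.01, the latter with a mean of 0.09. The lower values of these genes are therefore not particular to IL-6. No list passed for IL-6, the smallest adjusted p being 0.17.

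The difference between the lines in the cytokine response was fitted with the LIF and IL-6 arrays of each line as treated arrays, on the assumption that the lone control array varies as they do. No gene passed by limma, with a smallest adjusted p of 0.25, and 321 genes had an unadjusted p under 0.05. On simulated data this fit recovered 0% of 200 genes changed 4-fold. The simulated scatter came from the additive fit, which counts a difference between the lines in response as scatter. The 0% therefore does not give the power of this fit on these data. Leaving out the HTR-8/SVneo LIF array gave 34 genes, the JEG-3 LIF array 6, the JEG-3 IL-6 array 3 and the HTR-8/SVneo IL-6 array 2.

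The LIF and IL-6 responses were alike across genes in JEG-3, with r = 0.786 over 3414 genes and a covariance of 0.191. Unchanged arrays that share a control gave a simulated r of 0.502 and a covariance of 0.065. In HTR-8/SVneo r was 0.230 and the covariance 0.017, below the simulated 0.501 and 0.059. The simulated scatter was that of LIF minus IL-6, with an SD of 0.342 in HTR-8/SVneo. This exceeds the SD of 0.280 for LIF and 0.266 for IL-6 minus control, from which the lower values follow. In JEG-3, 277 genes were higher with both cytokines, against 73.0 for independent lists and 43.6 for unchanged arrays, and 113 were lower with both, against 19.5 and 42.8. Relative to the median gene these were 188 and 175. In HTR-8/SVneo 12 were higher with both and 9 lower, against 1.16 and 1.46 for independent lists and 36.7 and 36.2 for unchanged arrays. With a single control array per line the controls could not be split, and part of any excess may come from the shared control. Between the lines, the LIF responses correlated at r = 0.256 and the IL-6 responses at −0.279. The IL-6 response of JEG-3 correlated with the LIF response of HTR-8/SVneo at 0.381, so the 0.256 is not particular to LIF. For LIF in JEG-3 and IL-6 in HTR-8/SVneo r was −0.156. The signs of these correlations between the lines went with the shifts of the array medians against control. Those shifts were −0.254 for LIF and −0.310 for IL-6 in JEG-3, and −0.061 and 0.075 in HTR-8/SVneo. Responses and differences between arrays cannot be told apart here, so the −0.279 does not show opposite responses to IL-6. Genes are not independent replicates in these correlations.

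JEG-3 against HTR-8/SVneo compares the lines over 3 arrays each, with treatment as a term. In JEG-3 EPCAM and ELF3, which epithelial cells express, were higher by 4.37 and 3.69, with means of 4.26 and 0.81 over their probe sets, and GRHL1, an epithelial transcription factor, by 3.56. The epithelial junction gene CLDN1 went the other way at −0.81 (adjusted p = 0.0061 by limma), and the cell adhesion and junction list did not pass (camera adjusted p = 0.96). EPCAM had a mean of 11.56 ± 0.08 in JEG-3 and 7.19 ± 0.27 in HTR-8/SVneo (SD, n = 3 arrays per line). TP63 was higher by 2.48, the 1 gene called of 5 in the list of trophoblast transcription factors and keratins (camera adjusted p = 0.18), and PPARG, a nuclear receptor needed for trophoblast differentiation, by 2.05, the 1 gene called of 6 in the syncytiotrophoblast fusion list (adjusted p = 0.45). Also higher were CCBP2, a chemokine-scavenging receptor now named ACKR2, by 6.89, MGAT4A, a glycosyltransferase, by 5.40, MYCN by 4.55, ZIC1 by 4.39, DPP4, a surface peptidase, by 4.12 and LRP2, the endocytic receptor megalin, by 3.44.

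Some matrix and mesenchymal genes were higher in HTR-8/SVneo, while FN1 at −0.06, LAMC1 at 0.49 and S100A4 at 0.06 were not called. Differences as JEG-3 minus HTR-8/SVneo were −6.29 for TM4SF1, a membrane protein of migrating cells, −6.25 for EFEMP1, a matrix fibulin, −3.89 for SERPINE2, −3.48 for the adhesion molecule ALCAM, −2.83 for COL5A2 and −2.76 for ZEB2. TM4SF1 had a mean of 6.14 ± 0.26 in JEG-3 and 12.43 ± 0.12 in HTR-8/SVneo (SD, n = 3). HLTF, a chromatin remodelling gene that is silenced in some tumours, differed by −6.26 and TXNIP, which restrains glucose uptake, by −5.14. Each difference named between the lines has an SE of 0.24, and the largest adjusted p among those past 2-fold by limma was 1.4e-06, for COL6A3 at −1.30, which had a mean of −0.20 over its 54 probe sets.

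Between the lines 170 genes were at least 2-fold higher in JEG-3 and 190 lower at an adjusted p of 0.05 by limma, and 672 genes passed at any size. Over the lists fixed beforehand, extravillous trophoblast genes were lower in JEG-3 (camera adjusted p = 0.00065), with NOTCH2 and SERPINE2 called of 3 measured. The metalloproteinase, inhibitor and plasminogen list (adjusted p = 0.0074, SERPINE2 called of 3), extracellular matrix (adjusted p = 0.044, COL5A2 and COL6A3 of 6) and mesenchymal markers (adjusted p = 0.049, ZEB2 of 5) were lower too. The first of these measured no matrix metalloproteinase, only SERPINE2, PAPPA2 at −0.46 and TIMP4 at −0.18. It shares SERPINE2 with the extravillous list, so the 2 calls are not independent. p53 targets were higher (adjusted p = 0.044), with BTG2 at 2.45, ZMAT3 at 1.70 and SESN2 at 1.5 called of 7. None of the 5 lists passed with an estimated correlation (adjusted p = 0.51 for each). With 2 residual degrees of freedom few lists could pass that version, so it cannot tell whether correlation among genes accounts for the calls. HK2, hexokinase 2, was higher in JEG-3 by 1.43. With the mean over probe sets 411 genes were called, including 234 of the 360.

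**Figure D3:**
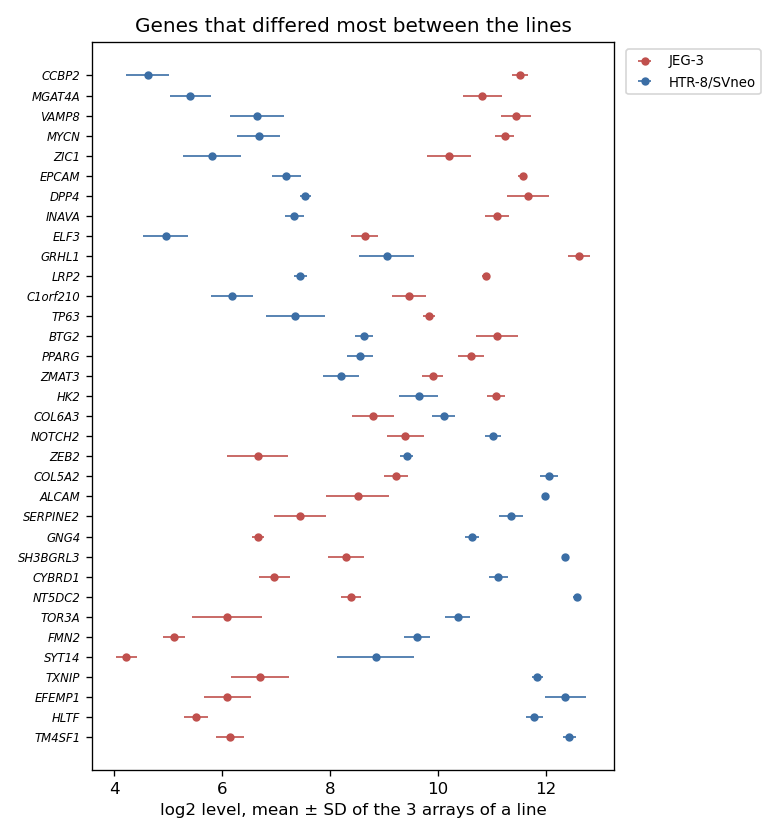
Mean log2 signal (horizontal axis) with its SD over the 3 arrays of JEG-3 (red) and the 3 of HTR-8/SVneo (blue) for the genes named between the lines. CCBP2 lies highest in JEG-3 relative to HTR-8/SVneo, by 6.89, and TM4SF1 lowest, at −6.29.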

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

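All tests in this part were chosen after the results were seen. Opposite directions in the 2 lines drew attention to 5 results on single arrays, and the differences between the lines were not tested. FCMR, a receptor for IgM, had an IL-6 minus control difference of 1.67 in JEG-3 and −0.74 in HTR-8/SVneo. LEPR, the leptin receptor, had −1.70 and 0.97 in the same comparison, with 4 and 19 of its 24 probe sets higher. For LIF minus IL-6, SPAG17, a protein of the ciliary axoneme, had 1.87 in JEG-3 and −3.40 in HTR-8/SVneo, with means of 0.06 and −0.11 over its 58 probe sets. UPK1B, a uroplakin, had −1.81 and 1.51, but its median over 12 probe sets was 0.07 in JEG-3, so that the opposite direction was lost there, and FCMR had −0.60 and 1.29 in that comparison.

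More genes passed 1.5-fold against control in JEG-3 than in HTR-8/SVneo, with 1091 against 127 for IL-6. Level-dependent scaling alone is argued against: after loess centring the spread over genes of IL-6 minus control in JEG-3 was still 1.59 times that of LIF minus IL-6. A gradient across genes that arrays of both lines share remains a candidate explanation of part of the excess, since IL-6 minus control in JEG-3 correlated with LIF minus IL-6 in HTR-8/SVneo at r = 0.534 (bootstrap interval 0.505 to 0.564), although these differences share no array. Removing a line fitted to a difference of the other cell line, an alternative chosen after seeing the data, cannot tell whether the gradient is the whole cause. The difference used for JEG-3 correlated at only 0.534 with IL-6 minus control and 0.335 with LIF minus control. A line on it could therefore remove only part of their spread. With the fitted line removed 710 genes passed for IL-6 in JEG-3 against 105 in HTR-8/SVneo, a ratio of 6.76 (bootstrap interval over genes 5.65 to 8.35) after 8.59. For LIF 421 passed against 110, a ratio of 3.83 (3.17 to 4.69) after 3.84. Each line was fitted to a difference of 2 single arrays and may remove too little. A response common to both cytokines and a deviating control array cannot be told apart with 1 control array, as either gives the correlation of 0.786 between the responses.

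The 57 genes higher with LIF than with control in HTR-8/SVneo include BCL6, SLCO2A1 and IL1RAP. Whether the shared gradient caused these calls cannot be told. With a line on the JEG-3 IL-6 minus control difference removed 43 of the 57 stayed past 1.5-fold, 62.2% to 85.9% by the binomial interval, but the genes were picked by the same difference, and the line follows a difference that correlated with it at only 0.381. Whether JEG-3 shares the LIF response of the set cannot be told. The set lay at percentile 0.115 of matched lists for LIF minus IL-6 in JEG-3, with 21 of the 57 above the median gene, but that difference cannot show a response that IL-6 also gives, and across all genes it correlated at −0.312 with the LIF response of HTR-8/SVneo. For LIF minus control in JEG-3 the set lay at percentile 85.5, with 36 of the 57 above 0, and the same correlation was 0.256. Of genes at least 1.5-fold higher, 10 were shared by the LIF responses of the lines, against 6.47 for independent lists, and of genes lower 23 were, against 4.07. Relative to the median gene these were 6 and 28. Single cross-hybridizing probe sets may explain part of the set and cannot be told apart from regulation by the median share of higher probe sets, 66.7% per gene (range 23.1% to 100% over the 56 genes with at least 3 probe sets), against 46.2% over all genes. A LIF response of HTR-8/SVneo itself stays open and was not tested.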

How the results depend on the processing

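The median over probe sets, the removal of a gradient shared by the lines, centring on the median gene, the fit to genes with at least 3 probe sets and the line contrast on treated arrays alone were chosen after seeing the data. The cause of a change was not tested unless the setting itself gives it. The 360 genes between the lines stayed between 346 and 411 under the other settings, and leaving out each array gave 366 to 387, while with no size threshold the count was 672. With treatment as a term, leaving out 1 array also takes the weight from the array of the same treatment in the other line. The 2 arrays of a treatment therefore gave the same count. For LIF over both lines the 4 genes became 8 with no level filter, 0 after quantile normalization, 0 after centring each array, 1 with the mean over probe sets, 1 with a mean-variance trend and 7 at an adjusted p of 0.2, and leaving out each array gave 0 to 22. For IL-6 the 1 gene became 4 with no level filter, 0 with the 70th percentile filter, 0 after quantile normalization, 0 after centring each array, 0 with the mean over probe sets, 0 with a mean-variance trend and 3 at an adjusted p of 0.2, and leaving out each array gave 0 to 5. The interaction count of 0 stayed 0 under every other setting, including an adjusted p of 0.2, but leaving out each treated array gave 2 to 34. It could not be fitted without a control array.

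Within the lines, a 2-fold threshold left 83 genes for LIF and 222 for IL-6 in JEG-3, 36 for LIF against IL-6 in JEG-3, and 16, 15 and 35 for the same comparisons in HTR-8/SVneo. Without a level filter 225 genes passed for LIF and 198 for IL-6 in HTR-8/SVneo, and with the 70th percentile filter 62 passed for IL-6. Quantile normalization gave 949 for LIF in JEG-3 and 380 for LIF against IL-6 in HTR-8/SVneo, and centring each array gave 983 for LIF in JEG-3. The mean over probe sets gave 40 for LIF against IL-6 in JEG-3 and 32, 14 and 86 for LIF, IL-6 and LIF against IL-6 in HTR-8/SVneo. The median gave 118 for LIF against IL-6 in JEG-3 and 81 and 63 for LIF and IL-6 in HTR-8/SVneo. With the shared gradient removed 710 passed for IL-6 in JEG-3, and CD2 there turned to −0.010. Of the other pairs of gene and control comparison kept for the text, 19 moved by at least the line's SD of LIF minus IL-6, and 54 did not. That SD was 0.358 in JEG-3 and 0.342 in HTR-8/SVneo. Of all 97 pairs kept, quantile normalization moved 16 that far, loess 8, the mean over probe sets 69 and the median 75. Few calls were shared between the summaries: 82 of the 519 for LIF and 289 of the 1091 for IL-6 in JEG-3, and 16 of 135 and 9 of 127 in HTR-8/SVneo, were also calls in the same direction with the mean over probe sets.

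The 4 correlations between responses kept their sign and stayed close to their values under the 5 other settings set beforehand. The alternative for linear values was not run, as the values are log2. No paired analysis was possible because each group has 1 array, and the line contrast already has treatment as a term. Signal over background cannot be judged from this table.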

Other observations

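All tests in this part were chosen after the results were seen. Markers of other cell types were few in the table. The leukocyte markers CD2 and PTPRC differed by 0.54 and 0.23 with LIF over both lines, and neither was called. COL3A1, which decidual stroma also expresses, was higher in JEG-3 with LIF by 0.65 and with IL-6 by 0.68, and differed by 0.06 and −0.16 in HTR-8/SVneo. The endothelial kinase TIE1 differed by 0.30 and 0.49 in JEG-3. The steroidogenic genes HSD3B1 and HSD3B2, which make progesterone, differed by 0.41 and 0.39 with LIF and by 0.31 and 0.53 with IL-6 in JEG-3, with none of the 3 listed genes past 1.5-fold.

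CHI3L1, a secreted chitinase-like protein that is induced in inflammation, was higher with LIF in HTR-8/SVneo in 14 of 15 probe sets, by 3.02 in their mean and by 0.997 in the brightest one. It was singled out after its values were seen.

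The 360 genes called between the lines can be set beside other ways of splitting the 6 arrays into 3 and 3. With 10 splits the share with as many genes cannot be under 0.05. The real split gave 360, the highest other split gave 0, and 1 of the 10 gave as many. Every other split mixed the lines, which puts their difference into the scatter. The 0 was therefore to be foreseen and says little about chance.

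On the IL-6 array of JEG-3 most of 24202 probe sets had a lower signal than on the control array, but less so at 1 end of genes. These were probe sets with a level of at least 8 on some array, in genes of chromosomes 1 to 3 with at least 10 probe sets. They were put in order by their identifiers, turned round for the second run of identifiers on each chromosome, and split into 5 bins per gene. The median difference was −0.17 in the first bin and −0.48 to −0.55 in the others, so that the first bin lay 0.33 above the rest (bootstrap interval 0.30 to 0.37 over 2304 genes). The first bin also lay nearer 0 than the others in the other 5 comparisons within a line, at −0.11 against −0.30 to −0.335 for LIF in JEG-3, at −0.063 against −0.17 to −0.20 for LIF against IL-6 in HTR-8/SVneo and, where signals were higher, at 0.035 against 0.089 to 0.108 for IL-6 in HTR-8/SVneo. It thus followed the shift between arrays less whatever its direction, and the pattern is not particular to JEG-3. Whether RNA breakdown graded along the transcript is the cause cannot be told. For IL-6 minus control in JEG-3 the second and the fifth bin differed by 0.067 (interval 0.041 to 0.094), a small part of the step at the first bin. For LIF against IL-6 in JEG-3 the bins rose steadily from 0.008 through 0.113, 0.128 and 0.165 to 0.202, and the second and the fifth differed by 0.090 (interval 0.070 to 0.113), which goes with a graded difference on the IL-6 array. Which end of the genes the first bin is was not settled, and no biological explanation was tested.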
